A study of Mus musculus with 30 samples.

How the data were processed

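Gene expression of cultured limb mesenchyme from CD-1 mouse embryos of stage E10.5 was measured on 30 Affymetrix Mouse 430 2.0 arrays, each carrying 45101 probe sets. Groups were taken from the labels: 3 populations (early, distal hindlimb; intermediate, distal forelimb; late, proximal forelimb), control medium at days 0, 1 and 2, and BMP4 at 20 ng/ml from the start of culture at days 1 and 2. The 15 groups hold 2 arrays each. Per the labels' protocols, RNA came from cultures of about 280 embryos, and 1 ug of RNA was labelled without amplification. The protocol text also mentions cultures of a later embryonic stage, and no array is placed there by its labels. The labels describe the arrays of a group as biological replicates.

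The deposited values are linear signal intensity from the MAS5 algorithm, per the submitters' processing notes. The settings of that step are not given in the sources used here. The trimmed mean of each array is 150, so the deposited intensity was scaled to a common level. The median signal per array ranged from 33.9 to 46.4 and the highest signal from 5456 to 8282. No detection calls were used here, so dim genes could not be marked as absent, and differences of dim genes are understated on the scale used. The 3' over 5' ratio of the control probe sets ranged from -0.50 to -0.01 on the log2 scale for Gapdh and from 0.10 to 0.41 for Actb. The principal components of the tested genes took 39.4% and 12.8% of the variance.

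The values were used as log2(signal + 16) without further scaling. A probe set was kept when it lay above its array's 40th percentile, which was a signal of 20.3 to 30.5, on at least 2 arrays. Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol, 932 several and 9160 none. Symbols came from the platform annotation, of which 34741 were matched by gene number to a gene table of assembly GRCm38.p6, with 0 renamed. No coordinates are given. The filter kept 33198 probe sets, 27577 of them with 1 symbol, and the brightest probe set of each gene was used, which left 15136 genes. Other probe sets of the named genes were fitted too, and 0 of them passed the threshold in the opposite direction. Some differed in sign without passing it. Only 1 of 2 others shared the sign for Lrig1 (BMP4, early day 1), Mtm1 (BMP4, intermediate day 1) and Ptch1 (early minus intermediate response, day 2).

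Tests were made with limma 3.58.1 in R 4.3.3, with a mean for each of the 15 groups and no block for the replicate number, in 1 fit of all 30 arrays (15 residual degrees of freedom, 5.51 prior degrees of freedom), moderated standard errors with a mean-variance trend, and Benjamini-Hochberg adjustment over all genes within a comparison at a threshold of 0.05, two-sided. The 18 planned comparisons were BMP4 against control in each population and day, the difference of that response between each pair of populations, the populations at day 0, and day 2 against day 0 in control cultures. Population comparisons in the 3 pairs of day 1 control cultures were added after seeing the data. Fit, filter, lists and the rule for named genes were chosen before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall past the threshold for each BMP4 comparison, the 8 largest each way for the others, up to 4 members with the smallest adjusted p for each list, and always Sox9, Col2a1, Acan, Id1, Smad6, Msx2, Gata3, Pitx1, Tbx4 and Tbx5. Meis2 and the cardiac genes of the closing section were chosen after their values were seen.

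The 29 gene lists were fixed from textbook knowledge: BMP targets and feedback; BMP ligands, receptors and SMADs; chondrogenic transcription factors; cartilage matrix; hypertrophy and bone; joint interzone; tendon and fibrous tissue; skeletal muscle; smooth muscle; endothelium; red blood cells; macrophages and leukocytes; ectoderm and apical ridge; nerve and Schwann cells; distal limb and FGF response; proximal limb; HoxA and HoxD; hindlimb identity; forelimb identity; hedgehog and posterior limb; TGF-beta and activin; WNT; Notch; retinoid; GATA factors; cell cycle; apoptosis and p53; hypoxia and glycolysis; and immediate early genes. Of 479 different genes in the lists 431 were tested, and 31 were not matched to the array and were not analysed here. Each list was tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over the 29 lists of a comparison.

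The procedure was tested on simulated data for 15136 genes with 200 changed. For BMP4 in the early population at day 2 it called 48%, 90%, 96% and 100% of genes changed by 1, 1.5, 2 and 3 on the log2 scale. Of all its calls 5.11% were false. For the early minus late difference at day 2 it called 28%, 70%, 82% and 100%, and 4.11% of its calls were false. The simulated noise was independent between genes and held no shift shared by arrays of a replicate number. These shares therefore need not hold for the measured arrays. Alternatives changed 1 choice at a time: quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, no variance trend, the replicate number as a block, only the arrays compared, and each array left out in turn. A fit that leaves out 1 array of a group of 2 assumes that the remaining array varies like the other groups. Fits without 3 doubted day 0 arrays, and without all 6 day 0 arrays, were added after seeing the data. Raw scan files were not used here.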

Results

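Gene expression was measured on 30 microarrays of limb mesenchyme, the loose embryonic tissue from which limb cartilage forms. The cells came from mouse limb buds at stage E10.5 and were kept in culture. Cells of the distal hindlimb are called the early population in the labels, cells of the distal forelimb the intermediate population, and cells of the proximal forelimb the late population. Each population was sampled at day 0 in control medium, and at days 1 and 2 in control medium and in medium with 20 ng/ml BMP4, a growth factor of the bone morphogenetic protein family. That makes 15 groups of 2 arrays, described in the labels as biological replicates, each from cultures of about 280 embryos. The median signal of an array lay between 33.9 and 46.4. The replicates of a group correlated with r between 0.970 and 0.984 across genes, which are not independent replicates. With 2 arrays per group, their number limits the precision of every comparison. Fold changes are differences of log2(signal + 16) with the standard error of the limma fit, and n is 2 arrays per group throughout. That error uses 1 spread per gene, shared over all 15 groups. It can understate the spread of a group with unequal replicates.

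Cartilage genes rose in control cultures of every population between day 0 and day 2. Col9a3, a chain of a cartilage collagen, rose by 6.06 ± 0.48 in the early population, and Matn4, a cartilage matrix protein, by 5.94 ± 0.59 in the early and 6.16 ± 0.59 in the intermediate population. Col2a1, the main collagen of cartilage, rose by 3.34 ± 0.51, 4.08 ± 0.51 and 3.17 ± 0.51 in the early, intermediate and late population. Sox9, the transcription factor that starts cartilage formation, rose by 1.48 ± 0.36 in the early and 1.01 ± 0.36 in the intermediate population, and its value of 0.87 ± 0.36 in the late population did not pass (adjusted p = 0.0801). In each population 22 of the 24 measured cartilage matrix genes rose (camera adjusted p = 9.81e-19, 4.06e-16 and 4.98e-14 in the same order; with an estimated correlation, adjusted p = 0.0436, 0.0829 and 0.0813). Chondrogenic transcription factors rose in 5, 7 and 3 of 12 members. Genes of hypertrophy and bone, such as those that cartilage turns on as it matures, rose in 6, 5 and 8 of the 8 measured members. Runx2, Spp1, Mmp13, Ibsp and Bglap were among the genes of this list that were not tested.

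Other cell programmes moved along with cartilage during the 2 days. Tendon and fibrous tissue genes rose in 13, 16 and 16 of 19 members and fell in 2, 1 and 1 in the early, intermediate and late population (estimated-correlation adjusted p = 0.0303, 0.00937 and 0.0058), and smooth muscle genes in 12, 13 and 12 of 14 (adjusted p = 0.0721, 0.0829 and 0.0813 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, rose by 5.65 ± 0.31 in the intermediate population, and Ogn, a matrix proteoglycan, by 6.07 ± 0.31 in the late population. Skeletal muscle genes rose in 11, 14 and 20 of 24 members (adjusted p = 0.361, 0.41 and 0.109 with an estimated correlation), with the myosin light chain Myl1 up by 6.30 ± 0.86 in the late population. Genes of red blood cells and vessels went down: the embryonic globin Hbb-bh1 changed by -7.26 ± 0.50, -7.17 ± 0.50 and -7.40 ± 0.50, red blood cell genes fell in 4, 5 and 6 of 9 members (adjusted p = 0.207, 0.235 and 0.169 with an estimated correlation), and endothelial genes fell in 9, 7 and 10 of 16 and rose in 0, 2 and 0 (adjusted p = 0.235, 0.41 and 0.218 with an estimated correlation). Genes of the distal limb and of the FGF response fell in 11, 13 and 11 of 22 members (adjusted p = 0.043, 0.0274 and 0.027 with an estimated correlation), among them Sall4, a factor of limb outgrowth, at -4.15 ± 0.40 in the intermediate and -3.35 ± 0.40 in the late population.

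Further lists described the same 2 days more briefly. HoxA and HoxD genes fell in 9, 4 and 5 of 16 members. Cell cycle genes fell in 9, 18 and 10 of 24 members and rose in 2, 1 and 1. Immediate early genes fell in 8, 6 and 7 of 18 members and rose in 1, 2 and 1. Genes of TGF-beta and activin signalling went both ways, with 9, 9 and 9 of 20 higher and 6, 4 and 6 lower. Genes of hypoxia and glycolysis rose in 7, 5 and 9 of 17 members, with 1 lower in the intermediate population. WNT signalling genes rose in 4, 7 and 5 of 23 members and fell in 6, 5 and 5. Apoptosis and p53 genes rose in 4, 6 and 4 of 13 members and fell in 2, 2 and 3, retinoid genes rose in 2, 4 and 3 of 13 and fell in 2, 3 and 2, and Notch genes rose in 0, 1 and 2 of 16 and fell in 1, 2 and 2. In total 2243 genes were higher and 1409 lower at day 2 in the early population, 2667 higher and 1922 lower in the intermediate population, and 2554 higher and 1611 lower in the late population, of 15136 tested. The count in the late population was 2521 without replicate 2 of its day 0 control, and 2550 without the 3 day 0 arrays in doubt that are described next. Each day 0 group holds 1 of those arrays, so a gene that differs between the populations has an uncertain change over time.

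At day 0, no gene passed the threshold between populations. The limma test called 0 genes for early against late, early against intermediate, and intermediate against late, with 336, 514 and 506 genes at an unadjusted p under 0.05 where 757 would be expected by chance. Other settings with all arrays gave at most 2, 2 and 1 genes, and leaving out 1 array at most 2, 2 and 6. The genes that tell hindlimb from forelimb did not follow the labels of the replicate 2 arrays labelled early and intermediate. Pitx1, a hindlimb transcription factor, read 9.74 on the log2 scale in replicate 1 of the early population and 5.90 in the array labelled early replicate 2. It read 6.15 in intermediate replicate 1 and 9.43 in the array labelled intermediate replicate 2. Tbx5, the forelimb counterpart, ran the opposite way, at 4.47 and 8.50 in the early arrays and at 8.47 and 4.68 in the intermediate arrays. In the arrays labelled late, Pitx1 was 6.11 and 6.12 and Tbx5 8.76 and 8.48, while Meis2, a gene of the proximal limb, was 9.60 in replicate 1 and 7.53 in replicate 2. Meis2 lay between 9.37 and 10.45 on all late arrays of days 1 and 2, and between 7.39 and 8.58 on all intermediate arrays of those days. The arrays are reported here by their labels. With the 3 replicate 2 arrays of day 0 left out, a choice made after seeing the data, 9, 18 and 37 genes differed in the same 3 comparisons.

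**Figure D1:**
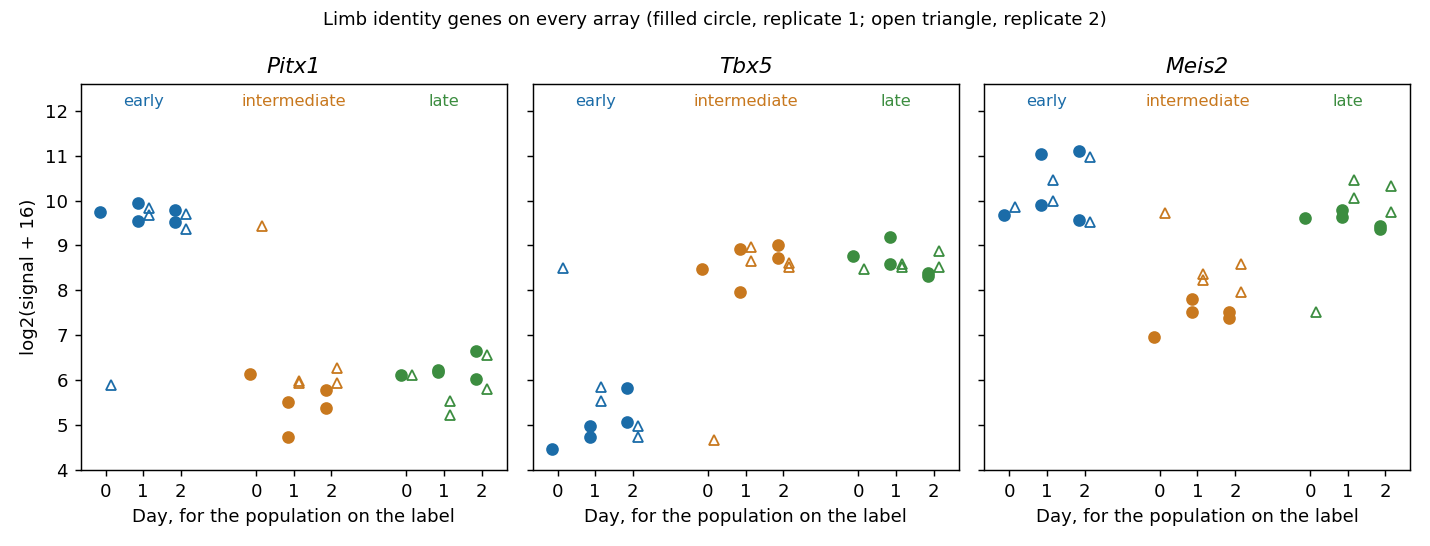
Log2(signal + 16) of Pitx1, Tbx5 and Meis2 on every array, by labelled population and day; filled circles are replicate 1, open triangles replicate 2. At days 1 and 2 each population keeps to its own levels, while at day 0 Pitx1 is 5.90 in the array labelled early replicate 2 and 9.43 in the array labelled intermediate replicate 2.

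Because of that doubt, the populations were also compared in the control cultures of day 1, a comparison added after seeing the data. Hindlimb genes were higher in the early population: Tbx4 by 4.32 ± 0.96 and Pitx1 by 4.10 ± 0.86 against the late population, with 2 of 6 hindlimb genes past the threshold (camera adjusted p = 2.85e-07, or adjusted p = 0.0746 with an estimated correlation). Against the intermediate population, also from the forelimb, neither passed, with Tbx4 at 4.17 (adjusted p = 0.137) and Pitx1 at 4.10 (adjusted p = 0.0918). Tbx5 was at -3.44 ± 0.93 against the late population and did not pass (adjusted p = 0.139). The doubted day 0 arrays stay in this fit and widen the errors of these genes, since Tbx5 had an SD of 2.85 in the early day 0 group. Without the 3 doubted arrays Tbx5 passed at the same value (adjusted p = 0.000132). Forelimb identity genes had 0 of 7 called, with all 7 below 0 (adjusted p = 6.16e-06, or adjusted p = 0.0991 with an estimated correlation). Skeletal muscle genes were lower than in the late population in both distal populations, 7 of 24 in the early and 8 of 24 in the intermediate population (adjusted p = 0.0552 and 0.0378 with an estimated correlation). Tnnt1, a troponin of slow muscle, was at -3.42 ± 0.73 in early against late cultures, and Tnnc2, a troponin of fast muscle, at -3.30 ± 0.75 in intermediate against late cultures. Lhx2, a factor of the distal limb, was higher in the intermediate population, by 1.66 ± 0.27 against the late population and with a difference of -2.04 ± 0.27 for early against intermediate. Proximal limb genes had 0, 0 and 1 of 16 lower in early against late, early against intermediate and intermediate against late cultures, the last being Emx2 at -2.27 ± 0.40. The doubted arrays widen the errors here too, since Meis2 had an SD of 1.46 in the late day 0 group. These low counts therefore do not show that proximal genes were alike in the populations. In total 12 genes were higher and 60 lower in early against late cultures, 4 higher and 4 lower in early against intermediate, and 18 higher and 83 lower in intermediate against late. Leaving out 1 array moved these counts: early against late gave 38 and 4 without early replicate 1 or 2 and 44 and 4 without late replicate 1 or 2, early against intermediate gave 0 and 3 without early replicate 1 or 2 and 0 without intermediate replicate 1, and intermediate against late gave 18 and 43 without intermediate replicate 1 or 2 and 66 and 17 without late replicate 1 or 2. Early against intermediate gave 26 genes without the 3 doubted day 0 arrays, and the smaller fit of the compared arrays alone gave 34 genes for early against late. A pseudocount of 1 gave 47 for early against late and 2 for early against intermediate.

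In the early population, 1 day of BMP4 raised known BMP target genes and a set of transcription factors. Tbx20, a T-box factor best known from the heart, rose by 4.57 ± 0.48 (limma adjusted p = 1.59e-05), from 5.60 ± 0.58 to 10.17 ± 0.46 (SD, n = 2). BMP target and feedback genes rose in 10 of 22 members, or 12 adjusted over the list alone, with Msx2 up by 2.81 ± 0.42, the secreted BMP antagonist Nog by 2.32 ± 0.30 and Id4 by 1.79 ± 0.30 (camera adjusted p = 1.43e-10; adjusted p = 0.00978 with an estimated correlation). Smad6, an inhibitor of the pathway, rose by 1.72 ± 0.30. Id1, a common BMP target, was at 0.01 ± 0.22 and did not pass. GATA factors and their cofactors rose in 4 of 7 members, among them Gata2 (1.00 ± 0.18) and Gata6 (2.70 ± 0.52), with adjusted p = 0.0606 with an estimated correlation. Gata3 was at 2.33 ± 0.75 (adjusted p = 0.115). Of the hedgehog and posterior limb genes 3 of 12 rose, the T-box factors Tbx2 and Tbx3 and the factor Hand1, by 2.82 ± 0.51, 2.49 ± 0.34 and 1.79 ± 0.44.

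Other genes that rose most at day 1 were Dlx2 (3.36 ± 0.55), the sialyltransferase St8sia4 (3.08 ± 0.22), the collagen Col14a1 (3.04 ± 0.37), the WNT antagonist Dkk1 (2.94 ± 0.32), the receptor Kit (2.94 ± 0.35), Edil3, Zfp804a, Plac8 and Rgs5. Those that fell most were the growth factor Fgf5 (-2.93 ± 0.49), Lrig1 (-2.83 ± 0.40), Galnt5, Osr2, the guidance cue Ntn1, Smoc2, Tbx18, the chemokine Cxcl12 (-1.91 ± 0.27), Mycn (-1.84 ± 0.26) and Lix1. Several of them mark the limb bud. Of 16 proximal limb genes 3 fell (Tbx18, Shox2 and Tbx15) and Meis3 rose. Of 22 distal limb and FGF response genes 2 fell, Mycn and Etv5, and of 10 joint interzone genes 2 fell, Osr2 and Sfrp2 (adjusted p = 0.0923 with an estimated correlation). Tendon and fibrous tissue genes rose in 3 of 19 members: Col14a1, Dcn (1.54 ± 0.27) and Postn (1.39 ± 0.29). Macrophage genes rose in 2 of 13 members, Tyrobp (1.14 ± 0.23) and C1qc (1.52 ± 0.40), or 9 adjusted over the list alone (adjusted p = 0.0492 with an estimated correlation).

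Of the 24 cartilage genes 2 rose at day 1 and 0 fell. Hapln1, a linker of cartilage proteoglycan, rose by 2.20 ± 0.36 and Fmod, a collagen-binding proteoglycan, by 1.77 ± 0.47. The list's median was -0.36 (camera adjusted p = 0.0268; adjusted p = 0.656 with an estimated correlation), and that call was lost without replicate 2 of the BMP4 group (median -0.12) and without replicate 1 of the control group (median -0.29). Sox9 read 9.66 and 8.06 in the BMP4 replicates against 9.66 and 9.51 in the controls, so the replicates differed more than the groups. In total 232 genes were higher and 139 lower with BMP4 at day 1, and 2274 had an unadjusted p under 0.05. Median centring gave 149 higher and 164 lower. The count of 371 fell to 163 without BMP4 replicate 2, to 105 without control replicate 1 and to 185 without control replicate 2, and was 83 when only the 4 arrays compared were fitted. Of 50 named genes past the threshold, 27, 25 and 35 stayed past it in those 3 fits with an array left out, and all 50 kept their sign.

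After 2 days of BMP4, cartilage matrix genes were lower in the early population than in its control cultures. Matn1, a cartilage matrix protein, fell by 3.41 on the log2 scale (± 0.52, limma adjusted p = 0.000892), from 10.14 ± 0.21 to 6.73 ± 1.83 (SD, n = 2). Cnmd, a cartilage protein that keeps vessels out, fell by 3.25 (± 0.57), from 9.86 ± 0.1 to 6.61 ± 1.43 (SD, n = 2). Of the 24 cartilage genes 13 fell and 0 rose, or 18 fell adjusted over the list alone, with a median of -1.46. The list's camera test gave adjusted p = 1.13e-13, and adjusted p = 0.138 with an estimated correlation. The fry test, which asks only whether the list's own genes move together, gave adjusted p = 0.00457. Acan, the main proteoglycan of cartilage, was at -1.47 ± 0.35 (adjusted p = 0.0157), while Sox9 at -0.98 ± 0.36 (adjusted p = 0.118) did not pass. Col2a1 read 11.63 and 10.25 in the BMP4 replicates against 11.89 and 11.99 in the controls and did not pass either (adjusted p = 0.281). Genes of cartilage maturation and bone fell in 4 of the 8 measured members, including the signal Ihh (-1.72 ± 0.28) and the factor Runx3 (-2.59 ± 0.52). That list's camera test gave adjusted p = 0.138 with an estimated correlation. Chondrogenic transcription factors fell in 2 of 12 members, Foxa3 and Foxc2. The BMP4 replicates were unequal: Acan read 7.58 and 6.24 against 8.49 and 8.28 in the controls, and without BMP4 replicate 2 the list's median was -0.95 and Acan was at -0.80 and no longer past the threshold.

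The genes that rose at day 2 overlapped with those of day 1. Tbx20 rose by 4.73 ± 0.48, Zfp804a by 3.11 ± 0.49, Gata6 by 3.01 ± 0.52, St8sia4 by 2.69 ± 0.22 and Nell1 by 2.64 ± 0.36, followed by Col14a1, Plac8, Slc26a7, Dlx2 and Dkk1. BMP target and feedback genes had 3 of 22 higher, Msx2 (2.27 ± 0.42), Dlx2 and Nog (1.30 ± 0.30), with adjusted p = 0.31 with an estimated correlation. GATA factors had 3 of 7 higher (adjusted p = 0.138 with an estimated correlation). Smooth muscle genes rose in 3 of 14 members, the smooth muscle actin Actg2 (2.44 ± 0.48), the coactivator Myocd (2.30 ± 0.51) and Myl9, with adjusted p = 0.315 with an estimated correlation. Tendon and fibrous tissue genes rose in 3 of 19 members, again Col14a1, Dcn and Postn. Of the hedgehog and posterior limb genes 4 of 12 rose, among them Tbx3 (1.85 ± 0.34) and Hand1 (2.01 ± 0.44), and 3 fell, among them the hedgehog receptor and target Ptch1 (-1.82 ± 0.34) and Bmp2 (-2.17 ± 0.29). BMP ligands, receptors and SMADs had 1 higher and 2 lower of 18, the lower ones being Bmp2 and Bmp7. Cell cycle genes fell in 11 of 24 members, with a median of -0.50 (adjusted p = 1.6e-13; adjusted p = 0.138 with an estimated correlation), among them Ccnd1 (-0.86 ± 0.17). Besides Matn1, Cnmd and Runx3, the genes that fell most were Mia, Galnt5, Matn4, Foxd2, Trim47, Bcl2 and Thsd4. The other probe set of Foxd2 and that of Thsd4 had the opposite sign without passing the threshold.

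Of the lists for other cell types, that of macrophages moved with BMP4 at day 2. Macrophage and leukocyte genes rose in 9 of 13 members, with a median of 1.28 (camera adjusted p = 2.78e-12; adjusted p = 0.00744 with an estimated correlation). The complement component C1qa rose by 1.40 ± 0.19, the signalling adaptor Tyrobp by 1.47 ± 0.23, the lysosomal protein Cd68 by 1.33 ± 0.23 and the lysozyme Lyz2 by 1.36 ± 0.26. C1qa was dim, at a mean of 4.34 on the log2 scale in the control and 5.74 in the BMP4 group. Endothelial genes had 0 of 16 called and a median of 0.09, red blood cell genes 0 of 9 and 0.15, skeletal muscle genes 0 of 24 and -0.17, and nerve and Schwann cell genes 1 of 9, Nefm at 2.33 ± 0.43. Without BMP4 replicate 2 the skeletal muscle median turned to 0.74 and its test passed (adjusted p = 0.00838), so the direction of that list was not settled. Ectoderm and apical ridge genes had 1 higher and 1 lower of 22. In total 364 genes were higher and 496 lower at day 2, and 3088 had an unadjusted p under 0.05. Median centring gave 239 higher and 784 lower. The count of 860 fell to 68 without BMP4 replicate 2, to 117 without control replicate 1 and to 367 without control replicate 2, and stood at 848 without BMP4 replicate 1. It was 168 when only the 4 arrays compared were fitted. Of 71 named genes past the threshold, 13, 21 and 44 stayed past it in those 3 fits and all 71 kept their sign.

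**Figure D2:**
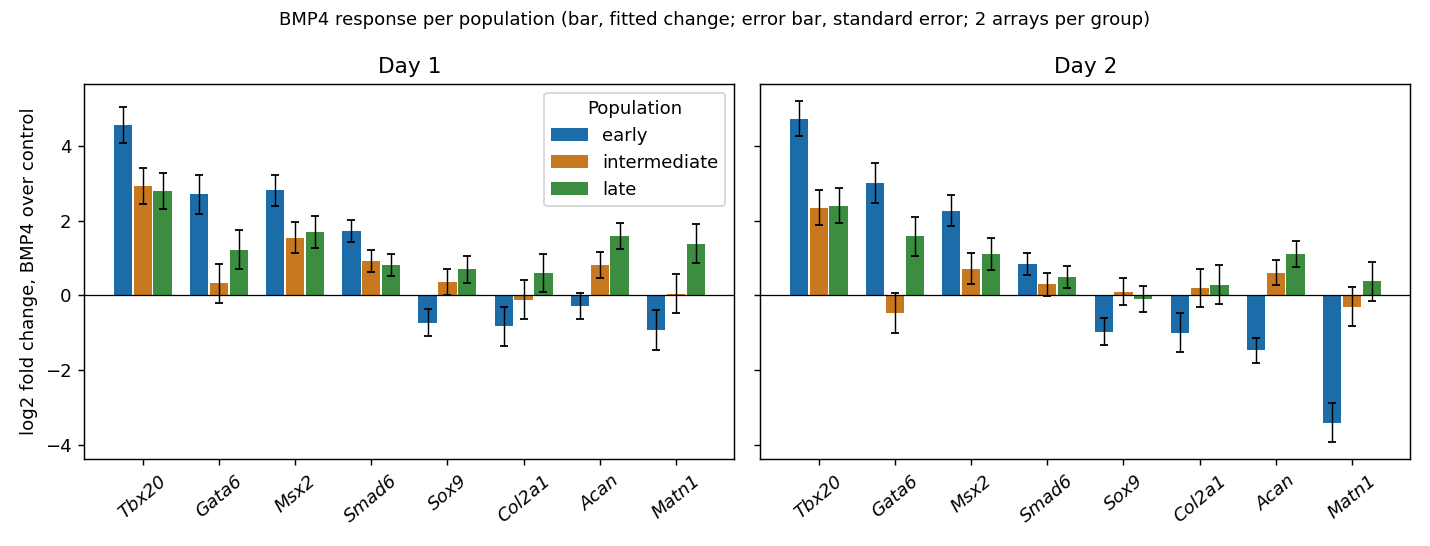
Log2 fold change of BMP4 over control (bars, with the standard error of the fit, n = 2 arrays per group) for Tbx20, Gata6, Msx2, Smad6, Sox9, Col2a1, Acan and Matn1 in the 3 populations at days 1 and 2. Tbx20 is the highest bar in the early population at both days (4.57 and 4.73), and Matn1 the lowest at day 2 (-3.41).

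In the intermediate population, day 1 of BMP4 raised part of the same genes. Dlx2 rose by 3.02 ± 0.55, Tbx20 by 2.92 ± 0.48, Col14a1 by 2.44 ± 0.37, Rgs5 by 1.98 ± 0.40, Dkk1 by 1.91 ± 0.32 and Nog by 1.86 ± 0.30, followed by Pcp4, the chordin-like BMP antagonist Chrdl2, Tbx3 and Sparcl1. Lix1 fell by 2.94 (± 0.48), Cxcl12 by 1.63 (± 0.27), Dsg2 by 1.58 (± 0.22) and the TGF-beta coreceptor Tgfbr3 by 1.44 (± 0.20), and smaller falls were seen for Tspan13, Tnfaip6, Hook1, Gas1, Mtm1 and Gsr. BMP target and feedback genes had 3 of 22 higher, or 7 adjusted over the list alone (adjusted p = 0.00919 with an estimated correlation). Macrophage genes had 1 of 13 higher, C1qa (0.99 ± 0.19), or 5 adjusted over the list alone (adjusted p = 0.0107 with an estimated correlation). The cartilage list had 0 of 24 called, and Acan was at 0.81 ± 0.35 (adjusted p = 0.587). In total 26 genes were higher and 10 lower, and 1134 had an unadjusted p under 0.05. The count of 36 became 104 without BMP4 replicate 1, 3 without BMP4 replicate 2, and 17 and 5 without control replicate 1 or 2, and was 0 with only the 4 arrays compared.

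At day 2 the intermediate population had 1 gene past the threshold, the matrix protein Sparcl1, which rose by 1.61 ± 0.26 (adjusted p = 0.0488). At an unadjusted p under 0.05 there were 686 genes. The 757 expected by chance assume p-values that are spread evenly when nothing changes, and the day 0 comparisons also fell under that number. A count under 757 therefore does not show that a response was absent. Acan was at 0.61 ± 0.35. Macrophage genes had 0 of 13 called, with 8 higher adjusted over the list alone and a median of 0.82 (adjusted p = 0.00526 with an estimated correlation). The Sparcl1 call was lost without any single array of the 4. The count of genes was 2 with quantile normalization, median centring, a pseudocount of 64 or no filter, and 0 with a pseudocount of 1, without a variance trend or with only the arrays compared.

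In the late population, BMP4 at day 1 raised Dkk1 by 2.95 ± 0.32, Tbx20 by 2.79 ± 0.48, Nog by 2.19 ± 0.30, Col14a1 by 2.19 ± 0.37, Kcns1 by 1.66 ± 0.30 and Tnfrsf11b, a decoy receptor of the bone-resorbing pathway, by 1.57 ± 0.21, with smaller rises for Mbnl1, Kif26b and Zfp704. Gsr, an enzyme of glutathione recycling, and Mtm1 fell, by 0.89 (± 0.15) and 0.82 (± 0.14). BMP target and feedback genes had 1 of 22 higher, or 9 adjusted over the list alone (adjusted p = 0.0243 with an estimated correlation). All 24 cartilage genes had a value above 0, with a median of 0.82. The test called 0 of them, or 6 adjusted over the list alone, and the list's camera test gave adjusted p = 1.38e-09, or adjusted p = 0.362 with an estimated correlation. Acan was at 1.59 ± 0.35 (adjusted p = 0.0703) and Sox9 at 0.70 ± 0.36 (adjusted p = 0.696). Macrophage genes had 0 of 13 called. In total 10 genes were higher and 2 lower, and 1144 had an unadjusted p under 0.05. The count of 12 became 4 and 1 without BMP4 replicate 1 or 2 and 28 and 2 without control replicate 1 or 2, and was 23 without the 3 doubted day 0 arrays. It was 20 with quantile normalization or median centring, 28 with a pseudocount of 64, 24 without a variance trend and 21 with only the arrays compared.

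At day 2 the late population had 2 genes past the threshold. Chadl, a small matrix protein related to chondroadherin, rose by 1.80 ± 0.23 (adjusted p = 0.00251), and Fam25c fell by 1.53 (± 0.24, adjusted p = 0.0249). Chadl was dim in the control group, at a mean signal of 18.3, and Fam25c in the BMP4 group, at 6.64. At an unadjusted p under 0.05 there were 712 genes. That is under the 757 expected by chance, which, as for the intermediate population, does not show that a response was absent. Of the 24 cartilage genes 22 lay above 0, with a median of 0.44, and 0 were called, or 2 adjusted over the list alone (adjusted p = 4.33e-07; adjusted p = 0.461 with an estimated correlation). Acan was at 1.12 ± 0.35 (adjusted p = 0.779). The count became 4 and 0 without BMP4 replicate 1 or 2 and 1 without control replicate 1. Chadl stayed past the threshold without BMP4 replicate 1 or control replicate 2, while Fam25c did not stay past it in any fit with 1 array left out. The count was 10 with a pseudocount of 64, 8 with no filter and 7 without a variance trend, 1 with quantile normalization and without the 3 doubted day 0 arrays, and 0 with only the arrays compared.

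Whether BMP4 acted differently between populations was tested on the difference of the responses. At day 2 the cartilage genes separated the early from the late population. The early response minus the late response was -4.54 ± 0.81 for Cnmd, -3.79 ± 0.74 for Matn1, -3.24 ± 0.33 for Chadl, -3.17 ± 0.59 for Chad and -2.59 ± 0.49 for Acan. Chadl and Chad were dim in the early BMP4 group, at mean signals of 15.8 and 6.19. Of the 24 cartilage genes 5 were lower in this difference, or 21 adjusted over the list alone, with a median of -2.05 (camera adjusted p = 5.07e-22; adjusted p = 0.0499 with an estimated correlation; fry adjusted p = 0.00882). Macrophage genes had 1 of 13 higher, C1qa at 1.38 ± 0.28, or 8 adjusted over the list alone (adjusted p = 0.0225 with an estimated correlation). Of all genes 11 were higher and 21 lower in the early minus late difference at day 2. Median centring gave 7 higher and 28 lower, after a shift of -0.12 in the median of all genes. That count of 32 dropped to 1 without early BMP4 replicate 2, early control replicate 1 or early control replicate 2, to 2 without replicate 1 of either late group, and to 8 without late BMP4 replicate 2, and rose to 99 without early BMP4 replicate 1. It was 1 with only the arrays compared and 1 with a pseudocount of 1, and of 17 named genes 1 stayed past the threshold in each of those fits.

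Against the intermediate population, the early response at day 2 was higher for Gata6 (3.48 ± 0.74), Slc26a7 (2.85 ± 0.59) and Kit (2.61 ± 0.50), and lower for Kcns1 (-2.53 ± 0.42), Bcl2 (-2.53 ± 0.52), Ptch1 (-2.38 ± 0.49) and Bmp2 (-1.99 ± 0.41). Kcns1 was dim in the early BMP4 group, at a mean signal of 2.2. In that difference 19 genes were higher and 22 lower, while median centring gave 11 higher and 25 lower. The cartilage list had 0 of 24 called and 15 lower adjusted over the list alone, with a median of -1.70 (adjusted p = 0.193 with an estimated correlation). The count of 41 fell to 0 without early BMP4 replicate 2, to 1 and 5 without early control replicate 1 or 2, to 0 and 8 without intermediate BMP4 replicate 1 or 2 and to 3 and 12 without intermediate control replicate 1 or 2, and rose to 104 without early BMP4 replicate 1. It was 65 with a pseudocount of 64, 27 without a variance trend, 5 with only the arrays compared and 3 with a pseudocount of 1. At day 1, St8sia4 and Gpr22 responded more in the early than in the late population (differences of 2.56 ± 0.31 and 2.54 ± 0.37). Gpr22 was dim in the early control group, at a mean signal of 3.59. Against the intermediate population the differences were 2.58 ± 0.31 and 2.62 ± 0.37 in the same order, and 4 genes passed in each comparison. Against the late population that count became 8 without early BMP4 replicate 1, and 10 and 1 without late control replicate 1 or 2. Against the intermediate population it became 7 and 1 without early BMP4 replicate 1 or 2, 2 and 8 without early control replicate 1 or 2, 1 and 7 without intermediate BMP4 replicate 1 or 2, and 7 without intermediate control replicate 2. Both were 0 with only the arrays compared and 1 with a pseudocount of 1, and early minus late gave 7 with no filter and 2 with the 60th percentile filter. Between the intermediate and late populations 0 genes differed at day 1, where 424 had an unadjusted p under 0.05, and 1 at day 2, Chadl at -2.21 ± 0.33 (adjusted p = 0.0198). Fits that lost the Chadl call included those with the 60th percentile filter (adjusted p = 0.0645), with a pseudocount of 1 (0.171), with only the arrays compared (0.473), without the 3 doubted day 0 arrays (0.0681), and those without either late BMP4 array, either late control array, intermediate BMP4 replicate 1 or intermediate control replicate 1.

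**Figure D3:**
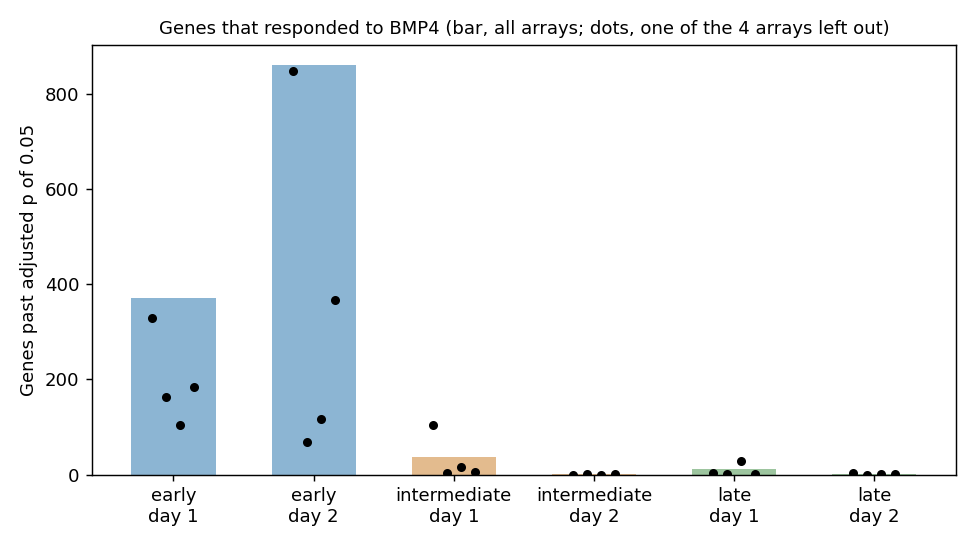
Number of genes past the threshold for BMP4 against control in each population and day (bars, all 30 arrays in the fit; n = 2 arrays per group), with dots for the same count when 1 of the 4 arrays compared is left out. The early population has 371 genes at day 1 and 860 at day 2, and its day 2 dots range from 68 to 848.

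Responses of different cultures shared no arrays and could be set side by side. All calls used the spread of each gene from the same fit. The numbers expected for independent lists are therefore a guide and no test. Of the genes called in the early population, 105 were higher at both days and 55 lower at both days, where independent lists would share 5.58 and 4.55, and 0 went opposite ways. The early and intermediate responses of day 1 shared 18 higher and 8 lower genes (0.399 and 0.0918 for independent lists), and 89.5% of the 371 early calls had the same sign in the intermediate population. In the late population of day 1 that share was 88.7%, with 7 shared higher and 2 shared lower genes. Of the 860 early calls of day 2, 71.0% had the same sign in the late population of day 2, where their medians were 0.21 for the early higher genes and -0.08 for the early lower ones, with 0 shared calls and 1 opposite call. Against the late population of day 1, the early calls of day 2 had 6 shared higher calls, 1 shared lower call and 2 opposite calls, and 73.7% had the same sign. Fold changes of all genes correlated across genes, which are not independent, with r = 0.54 between early days 1 and 2, r = 0.48 between the early and intermediate populations at day 1 and r = 0.16 between the early and late populations at day 2.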

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

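Of the tests in this part, those of a single array and of scaling for the macrophage genes were chosen before their results were seen, and the tests of labels, mixing, spread, scaling for the count of genes and cell share were chosen only afterwards.

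The results below stood out because a test of the difference between populations in their BMP4 response passed its threshold. For early minus late at day 1, 4 genes passed: St8sia4 at 2.56, Gpr22 at 2.54, Dnah7a at 2.48 and Trim47 at -2.31. For early minus intermediate at day 1, 4 genes passed: Gpr22 at 2.62, St8sia4 at 2.58, Ralyl at 2.24 and Sparcl1 at -2.32. For intermediate minus late at day 2, 1 gene passed, Chadl at -2.21. Fits that lost that call, with a count of 0, included the fit of only the arrays compared, the 60th percentile filter and the fits without day 0 arrays, and leaving out 1 array gave 0 to 3 genes.

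For early minus late at day 2, 32 genes passed. The largest positive differences were those of Cntn4 (2.24), Gpr22 (2.20), Glra2 (2.01), St8sia4 (1.90), Zdhhc11 (1.80), Slc15a3 (1.74), Cd53 (1.68) and C1qa (1.38). The largest negative ones were those of Cnmd (-4.54), Matn1 (-3.79), Chadl (-3.24), Chad (-3.17), Ncmap (-2.82), Acan (-2.59), Trim47 (-2.49) and Col11a2 (-2.44). In the early control group Cntn4, Gpr22, Glra2, Zdhhc11, Slc15a3 and C1qa were dim, at mean signals of 3.74, 2.63, 0.925, 13.4, 2.56 and 4.29. In the early BMP4 group Chadl, Chad and Ncmap were dim, at 15.8, 6.19 and 4.82.

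For early minus intermediate at day 2, 41 genes passed. The largest positive differences were those of Gata6 (3.48), Slc26a7 (2.85), Adamts8 (2.61), Kit (2.61), Prdm6 (2.28), Slitrk5 (2.28), Cntn4 (2.27) and St8sia4 (2.10). The largest negative ones were those of Kcns1 (-2.53), Bcl2 (-2.53), Agtr1a (-2.45), Ptch1 (-2.38), Trim47 (-2.10), Sparcl1 (-2.09), Bmp2 (-1.99) and Lbhd2 (-1.98). Slitrk5 and Cntn4 were dim in the early control group, at mean signals of 7.92 and 3.74, and Kcns1 in the early BMP4 group, at 2.2.

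More genes responded to BMP4 in the early than in the late population at day 2 (860 against 2, where other settings with all arrays gave at most 10 for the late population). A larger spread among the late arrays was excluded, since the SD of the difference between replicates was 0.88 times that of the early arrays. The early BMP4 group had the larger spread at day 2 (0.415, late 0.325), while the control groups were alike (0.346 and 0.344). Each gene's spread was shared over all 15 groups, so the errors of the early comparison reflect this only in part. Whether that raised the early count was not tested. Scaling between arrays was excluded, since 937 early genes passed after quantile normalization. A single array cannot be told apart from a population difference as the source of the size of the count, because the lowest count with 1 of the 4 early arrays left out was 68. That met the bound of 50 set beforehand, but the bound was too low to exclude a single array: 860 fell to 68, though also to 117 without control replicate 1, and the tested difference fell from 32 genes to 1. A different BMP4 response of distal hindlimb and proximal forelimb cells stays open as the biological explanation.

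Macrophage and leukocyte genes were higher in early BMP4 cultures at day 2. A lower share of mesenchymal cells that raises every other cell type alike would move both medians together, but the macrophage median exceeded the endothelial median by 1.19. The 95% bootstrap interval of that difference ran from 0.77 to 1.32. With 2 arrays per group it does not measure the spread between cultures. A rise of dim endothelial genes would also be understated on this scale, so a change in cell share was not excluded. Scaling between arrays was excluded, since the list's median was 1.10 after quantile normalization and its test stayed past the threshold. More macrophages in those cultures, or higher expression in the same number, stay open, and neither was tested.

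The 3 replicate 2 arrays of day 0 carried limb identity genes of another population. Over 852 genes that separate the populations at days 1 and 2, the replicate 1 arrays of day 0 each correlated best with their labelled population (r = 0.44, 0.45 and 0.33 for early, intermediate and late), and 0 replicate 2 arrays did. The array labelled early correlated best with late (0.22, own -0.09), the array labelled intermediate with early (0.40, own -0.21) and the array labelled late with intermediate (0.39, own -0.10). Of the arrays labelled early and intermediate, 0 of 2 had both Pitx1 and Tbx5 over 7 on the log2 scale. That speaks only against a large share of both hindlimb and forelimb cells in an array. The bound was chosen after the values were seen, and a small share of other cells would stay under it, so a mixed sample was not excluded. A mixture was not tested for the array labelled late. A mislabelled sample fits, with the 3 labels shifted among the 3 populations, and no biological explanation was tested.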

How the results depend on the processing

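The fits without day 0 arrays and the comparisons of day 1 control cultures were chosen only after the results were seen; the other alternatives were planned. Named genes past the threshold kept their direction in every fit, but many lost their call. Outside fits with an array left out, 6090 results of called genes stayed past the threshold and 548 did not; with 1 array left out, 1663 stayed and 845 did not. For called lists, 1954 results stayed, 230 lost the call and 2 turned outside those fits; with 1 array left out, 678 stayed, 169 lost the call and 5 turned. A lone remaining array is assumed to vary like the other groups. Signal over background limits dim genes, whose changes are understated. The smaller fit has fewer residual degrees of freedom; for the other changes the cause was not tested.

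Counts with 1 array left out ranged for BMP4 from 105 to 329 (early day 1), 68 to 848 (early day 2), 3 to 104 (intermediate day 1), 0 to 2 (intermediate day 2), 1 to 28 (late day 1) and 0 to 4 (late day 2). For differences in response they ranged at day 1 from 1 to 10 (early minus late), 1 to 8 (early minus intermediate) and 0 to 4 (intermediate minus late), and at day 2 from 1 to 99, 0 to 104 and 0 to 3. At day 0 they ranged from 0 to 2 (early against late), 1 to 2 (early against intermediate) and 0 to 6 (intermediate against late), in day 1 controls from 4 to 44, 0 to 11 and 17 to 66, and over time from 2440 to 2985 (early), 3131 to 3619 (intermediate) and 2521 to 3363 (late).

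With only the arrays compared, BMP4 counts were 83 and 168 (early days 1 and 2), 0 and 0 (intermediate), and 21 and 0 (late). Early minus late gave 0 and 1, early minus intermediate 0 and 5, intermediate minus late at day 2 gave 0, and early against late in day 1 controls 34. With quantile normalization the intermediate day 2 count was 2, the late counts 20 and 1, and early against late at day 0 gave 1. Median centring gave 2 (intermediate day 2), 20 (late day 1) and 1 (early against late at day 0). A pseudocount of 1 gave 0 (intermediate day 2), 1 and 1 (early minus late), 1 and 3 (early minus intermediate), 2, 2 and 1 at day 0 in the order above, and 47 and 2 for early against late and against intermediate in day 1 controls. A pseudocount of 64 gave 2 (intermediate day 2), 28 and 10 (late), and 65 (early minus intermediate at day 2). No filter gave 2 (intermediate day 2), 8 (late day 2), 7 (early minus late at day 1) and 1 (early against late at day 0). The 60th percentile filter gave 2 (early minus late at day 1) and 0 (intermediate minus late at day 2). Without a variance trend, counts were 0 (intermediate day 2), 24 and 7 (late) and 27 (early minus intermediate at day 2).

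With the replicate number as a block, BMP4 counts were 575 and 1375 (early), 97 and 3 (intermediate) and 59 and 4 (late). The block gave 90 for early minus late at day 2, 9 and 75 for early minus intermediate, 0 for intermediate minus late at day 2, 1 for early against late at day 0, and 26 and 166 for early against intermediate and intermediate against late in day 1 controls. Replicate numbers correlated over 0.1 in 15 of 18 pairs of groups of days 1 and 2 (0.04 to 0.35), and from -0.12 to 0.17 with day 0, and replicate 2 lay lower than replicate 1 on the second principal component in all 15 groups. This is a hint from the data, and the labels do not say what a number shares.

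Without the 3 doubted day 0 arrays, late counts were 23 and 1, intermediate minus late at day 2 gave 0, day 0 gave 9, 18 and 37, the late count over time was 2550, and early against intermediate in day 1 controls 26. Without the 6 day 0 arrays, the late counts were 23 and 1, intermediate minus late at day 2 gave 0, and early against intermediate in day 1 controls 26.

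The value or the direction of its test turned in 27 results, each called in only 1 of the 2 fits. With 1 array left out, the median of skeletal muscle in early BMP4 cultures at day 2 (-0.167) ranged from -0.770 to 0.737, the highest without BMP4 replicate 2. For intermediate minus late at day 1, cell cycle ranged from -0.154 to 0.136 and smooth muscle from -0.419 to 0.296. For early against late at day 0, the ranges were 0.069 to 2.704 for hindlimb identity, -0.495 to 0.313 for endothelium, -0.083 to 0.518 for proximal limb and -0.122 to 0.119 for cell cycle, which was also 0.069 without late replicate 2. For early against intermediate they were -0.324 to 0.448 for endothelium, which was also -0.284 without early replicate 1, -0.920 to 0.715 for red blood cells, and -1.329 to 1.461 for hindlimb identity, which was also -1.120 without early replicate 1. For intermediate against late they were -0.694 to 0.796 for red blood cells, -0.815 to 0.065 for proximal limb, with 0.036 without intermediate replicate 1, -0.100 to 2.936 for hindlimb identity and -0.043 to 0.525 for distal limb. Without the 3 doubted arrays, early against late gave 0.198 for distal limb, -0.221 for proximal limb, -0.619 for forelimb identity and 0.199 for cell cycle. In that fit early against intermediate gave -0.321 for macrophages, 0.083 for cell cycle and 3.452 for Hoxc10 (-0.515 with all arrays), intermediate against late gave 0.172 for macrophages and 0.060 for hindlimb identity, and Tbx4 over time in the early population went from 1.049 to -1.098.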

Other observations

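The cardiac test and its gene lists, and the choice of the genes in this part, were made only after the results were seen.

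In the early population, BMP4 raised several transcription factors known from heart development, among them Tbx20, Gata6 and Hand1 at both days and Myocd at day 2. These genes were grouped after they had been seen to rise, so their number is no test of a cardiac response. Several also act in other tissues, limb bud mesenchyme among them, and Tbx20 rose in the intermediate and late populations at day 1 as well. A cardiac muscle programme was tested on the contractile genes of heart muscle and cannot be told apart from a response without it. At day 2, 0 of 12 passed the threshold and their median was 0.19, but 8 lay above 0 and 4 below, and 6 lay below the 40th percentile of signal on a control array.

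BMP4 cultures of the early population also differed between their replicates in cartilage genes. Col2a1 read 11.30 and 10.05 in the BMP4 replicates of day 1 against 11.56 and 11.45 in the controls. Sox9 read 9.20 and 8.44 at day 2 against 9.68 and 9.91. Replicate 2 was the lower array in each case.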
